A study of Mus musculus with 9 samples.

How the data were processed

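Chromatin immunoprecipitation with an antibody to Lamin B1, a filament protein of the nuclear lamina that lines the inner nuclear membrane, was followed by sequencing in whole hearts of mouse embryos of the CD1 stock. The series holds 9 samples, of which 7 Lamin B1 libraries had processed files: 4 from embryonic day 9.5 (E9.5) and 3 from embryonic day 12.5 (E12.5). Per the labels, each E9.5 sample pooled hearts from 3 litters and each E12.5 sample pooled 6 embryos. The 2 input libraries, 1 per age, were not analysed here. The series' design text calls the samples biological replicates.

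The deposited files are lists of domains called by the authors, 1 list per sample, each domain with a chromosome, a start and an end in bases and no score, signal or read count. Per the submitters' processing notes, Bowtie (version not stated) and genome build mm9 were used. The domain caller, its threshold and any use of the input are not given in the sources used here. The names of the lists all carry the number 800 and a further number that differs between samples (0.12 to 0.17 at E9.5, 0.12 to 0.13 at E12.5). The meaning of both is not stated, and a setting of the calling that differed between samples cannot be separated from the measures. All starts and ends were whole multiples of 1 kb, and no domains within a file overlapped. Every file listed exactly 1500 domains, and their summed length lay between 775.5 and 811.8 Mb. A number of domains that is equal in all files cannot be compared between samples, and with a nearly equal summed length a gain in one place comes with a loss in another. The depth of each library is unknown, so no counting interval or detection limit was given. The number of samples limits the precision.

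Each sample was turned into a row of 1-kb positions inside or outside a domain (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Overlap of 2 samples was measured by the Jaccard index, the bases in domains of both divided by the bases in domains of either. A domain was called matched in another sample when at least 50% of its length lay in domains of that sample. Chance overlap was measured by shifting a sample's domains along each chromosome by a random amount, wrapping at the end, which keeps domain lengths and spacing (200 rotations for the Jaccard index, 20 per sample for the matches by domain length, fixed seed). Age-specific regions were unbroken stretches inside the domains of every sample of one age and of no sample of the other.

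Ages were compared by exact permutation of the samples. The 7 samples split into 4 and 3 in 35 ways, so the smallest possible p is 0.0286. Differences of means were tested two-sided on their absolute size. The within-age excess of overlap was tested one-sided. The total length of age-specific regions was compared with the same total in the other 34 splits. No single position can pass a genome-wide adjustment in this design. Benjamini-Hochberg adjustment was applied over the 6 main tests, over 4 measures of domain length, over the 21 chromosomes and over the 2 chromosome ends.

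The script for age-specific regions was tested on simulated data made from the 1500 domains of E9.5 replicate 1, with edges moved by up to 30 kb in each simulated sample. With 40 regions of 300.0 kb inserted per age, 99.97% of the inserted E9.5 length and 99.93% of the inserted E12.5 length was recovered. Recovery close to the whole is expected by construction, since the simulated samples were copies of 1 list and each region was put in every sample of its age. It shows that the script works and not what share is found in samples that differ as much as these. The real split then ranked first of 35 in both directions. With no inserted region, 0.681 Mb was found in all E9.5 and no E12.5 simulated samples, and 19 of the 35 splits gave as much.

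The tests, the alternatives and the rule for named regions were fixed before the data were examined, with these exceptions. The rotations, the domain length classes, the counts of domains with no shared base, the singling out of the X from the planned comparison of all chromosomes, its alternatives, the counts of split domains, and the chromosome ends were added afterwards. Named regions are, per age, the 10 longest age-specific regions, and the 5 longest regions inside the domains of all 7 samples. Alternatives were leaving out each sample, keeping only domains of at least 100 kb, keeping chromosomes 1 to 19 only, joining domains less than 50 kb apart, group medians, the replicate number as a block, allowing 1 exception per age, a minimum region length of 50 kb, and other limits for a match. Coordinates are 1-based on mm9. The gene table at hand is of assembly GRCm38, and on 9 of the 21 chromosomes domains reached beyond its last gene. Genes were therefore not placed in domains, and the gene-level comparisons that had been planned were not run. The age of the embryos and the kind of pool (3 litters or 6 embryos) change together, so a difference between ages is also a difference between pools.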

Results

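Lamina-associated domains, the stretches of chromosome that lie against the nuclear lamina at the nuclear edge, were compared between mouse embryonic hearts at E9.5 (n = 4 samples) and E12.5 (n = 3 samples). The series asked where Lamin B1 sits on the genome at these 2 ages. The unit of measurement throughout is the length of chromosome inside the domains that the authors called in each sample. Every sample held 1500 domains, so their number appears to be set in the calling, and the covered length may be bound by it. The covered length was 792.1 Mb ± 15.04 (SD, n = 4) at E9.5 and 804.0 Mb ± 7.19 (SD, n = 3) at E12.5, a difference of 11.9 Mb that was within the spread of the samples (exact permutation test, two-sided, p = 0.229, adjusted over the 6 main tests 0.229). With 1 sample left out the difference ranged from 6.31 to 18.03 Mb. On chromosomes 1 to 19 alone the difference was -1.54 Mb. If the calling fixed the covered length, its test cannot show whether the total contact with the lamina changed. Read depth is unknown for these lists.

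Part of the covered length was held in every sample of both ages. In all, 1467 Mb lay in a domain of at least 1 sample, and 278.7 Mb lay in domains of all 7, which was 34.96% of the mean covered length. The shared length formed 874 regions with a median of 185 kb, and 52 of them were 1 Mb or longer. The longest was on chromosome 18 from 85681001 to 88970000, a stretch of 3289 kb. It was followed by 2571 kb on chromosome 2 from 174982001 to 177553000 and by 2341 kb on chromosome 8 from 19703001 to 22044000. The next were 2242 kb on chromosome 16 from 60105001 to 62347000 and 2173 kb on chromosome 17 from 18885001 to 21058000. Shared length made up 21.7% of chromosome 15 up to its furthest domain end, 18.03% of chromosome 16 and 16.4% of chromosome 3. It made up 5.63% of chromosome 9, 5.17% of chromosome 7, 4.32% of chromosome 13 and 1.33% of the X.

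Domain sets grouped by age. The Jaccard index averaged 0.603 between E9.5 samples (6 pairs, 0.561 to 0.664), 0.534 between E12.5 samples (3 pairs, 0.527 to 0.540) and 0.490 between ages (12 pairs, 0.448 to 0.530). Rotated domain sets gave 0.193 on average and at most 0.225 in 200 rotations. The within-age mean exceeded the between-age mean by 0.09, more than in any of the other 34 splits, of which the highest gave 0.03 (exact permutation test, one-sided, p = 0.0286, adjusted 0.0343). The margin was small for the E12.5 samples. E12.5 replicate 3 and E9.5 replicate 1 had an index of 0.530, above the lowest pair within E12.5. Among the E9.5 samples, replicate 3 had the lowest mean index with the E12.5 samples (0.455) and with its own age (0.568).

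**Figure D1:**
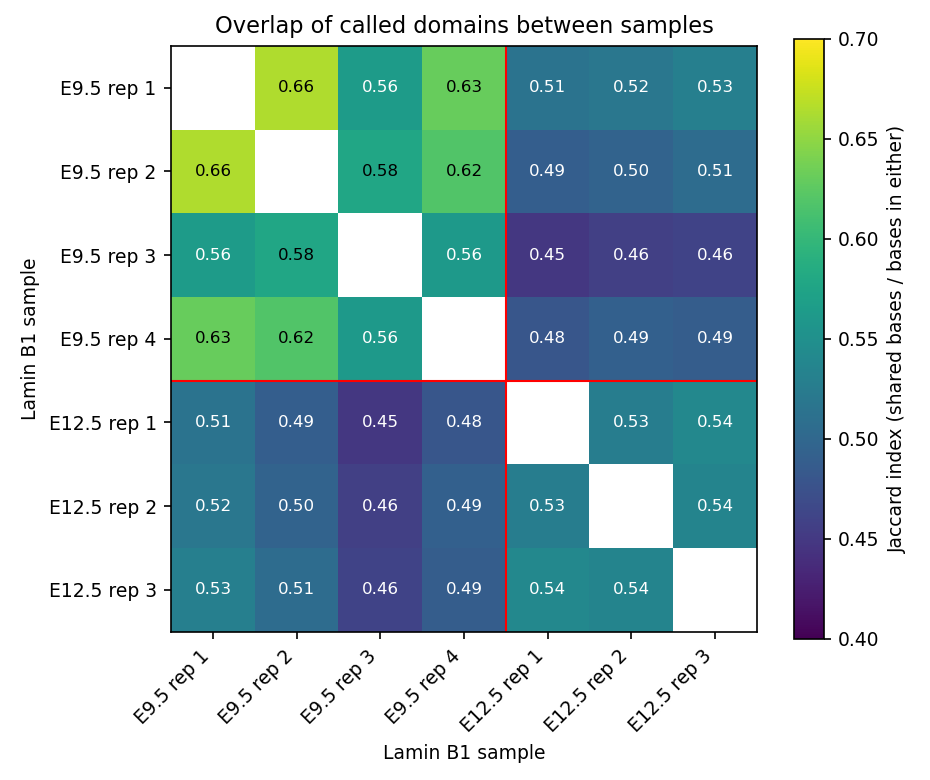
Jaccard index of called domains (shared bases over bases in either sample) for each pair of the 4 E9.5 and 3 E12.5 samples; red lines part the ages. Pairs within E9.5 lie between 0.561 and 0.664, pairs within E12.5 between 0.527 and 0.540, and pairs between ages between 0.448 and 0.530.

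Counted by domain, 51.1% of E9.5 domains were matched in an E12.5 sample (mean of 12 pairs, 46.9% to 57.2%). In other E9.5 samples 55.9% were matched. Of E12.5 domains, 51.1% were matched in an E9.5 sample and 56.9% in other E12.5 samples. The within-age share exceeded the between-age share by 5.16 percentage points (exact permutation test, one-sided, p = 0.0286, adjusted 0.0343), and the highest other split gave 3.19. Of the 1500 domains of an E9.5 sample, 308 ± 42.0 (SD, n = 4) shared no base with any of the 3 E12.5 samples. Against the 3 other E9.5 samples the number was 249 ± 55.5 (SD, n = 4). The number was higher against E12.5 in 4 of 4 samples, by 59 on average, which gives the smallest p that 4 samples allow (exact sign-flip permutation, two-sided, p = 0.125). The 4 differences share the same 3 E12.5 samples, and each E9.5 sample is in the comparison set of the others. They are not independent, so this p is only a rough guide.

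Some regions were inside the domains of every sample of one age and outside those of every sample of the other, which is called absent here. Regions held at E9.5 and absent at E12.5 numbered 276 and summed to 26.8 Mb, with a median of 65.5 kb. Regions held at E12.5 and absent at E9.5 numbered 259 and summed to 24.6 Mb, with a median of 64.0 kb. No other split of the 7 samples gave as much in either direction (1 of 35 splits, share 0.0286, adjusted 0.0343). The highest other split gave 12.2 Mb for the 4-sample part and 13.2 Mb for the 3-sample part, and the median of the other splits was 2.72 and 3.40 Mb. The lengths and the margin depend on the condition. With 1 exception allowed per age they were 149.5 and 180.1 Mb, where the highest other splits gave 127.0 and 130.3 Mb. With 1 sample left out they ranged from 30.9 to 44.6 Mb and from 31.7 to 48.1 Mb. The test is of the total length and not of any single region. The overlap, the matched domains and both age-specific lengths describe the same grouping of the same 7 samples and are not separate results.

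**Figure D2:**
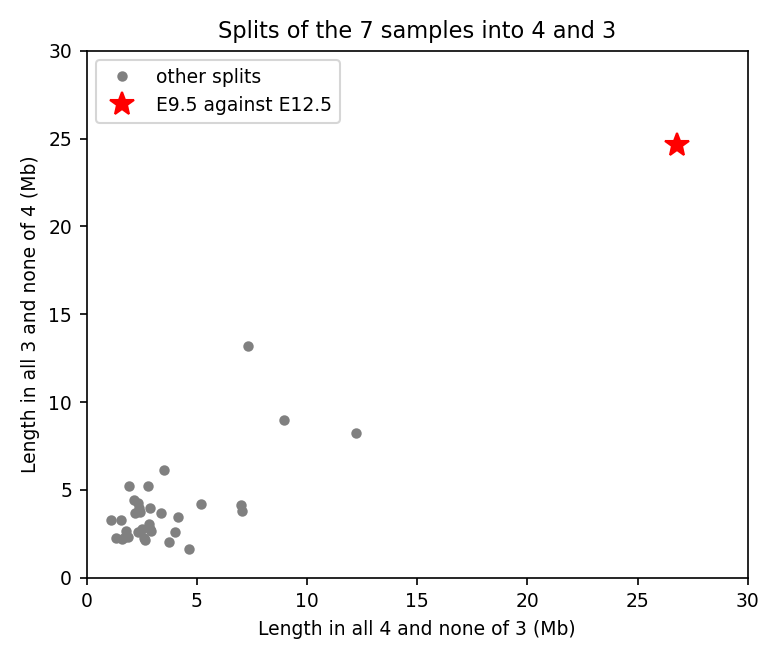
Each point is 1 of the 35 splits of the 7 samples into 4 and 3. The x axis gives the length in Mb inside the domains of all 4 and none of the 3, and the y axis the reverse; the split by age (red star, 26.8 and 24.6 Mb) stands apart from the others, which reach 12.2 and 13.2 Mb.

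The longest region held at E9.5 and absent at E12.5 covered 754 kb on chromosome 4 from 113175001 to 113929000. The second covered 586 kb on chromosome 14 from 50749001 to 51335000. The third covered 515 kb on chromosome 1 from 119524001 to 120039000. Chromosome 4 held 2 further regions of the 10 longest, one of 462 kb from 74170001 to 74632000 and one of 398 kb from 145655001 to 146053000. Chromosome 5 held 426 kb from 109208001 to 109634000 and 302 kb from 146540001 to 146842000. The remaining ones were 436 kb on chromosome 10 from 15598001 to 16034000, 345 kb on chromosome 6 from 89750001 to 90095000 and 308 kb on chromosome 13 from 86440001 to 86748000. Of the 10 regions, 3 had no E12.5 domain within 50 kb (the longest 2 and that of 398 kb), 4 had a domain of 1 E12.5 sample and 3 had domains of 2 E12.5 samples within that distance.

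The longest region held at E12.5 and absent at E9.5 covered 821 kb on chromosome 6 from 94389001 to 95210000. The X chromosome held 3 of the 10 longest. They covered 666 kb from 144348001 to 145014000, 649 kb from 3213001 to 3862000 and 427 kb from 25477001 to 25904000. Chromosome 4 held 496 kb from 103604001 to 104100000, and chromosome 8 held 384 kb from 15532001 to 15916000. Chromosome 11 held 337 kb from 56253001 to 56590000 and 305 kb from 80856001 to 81161000. The last of the 10 were 325 kb on chromosome 12 from 9256001 to 9581000 and 316 kb on chromosome 18 from 40323001 to 40639000. Of these 10 regions, 8 had a domain of 1 or 2 E9.5 samples within 50 kb, the longest among them, and 2 had none.

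**Figure D3:**
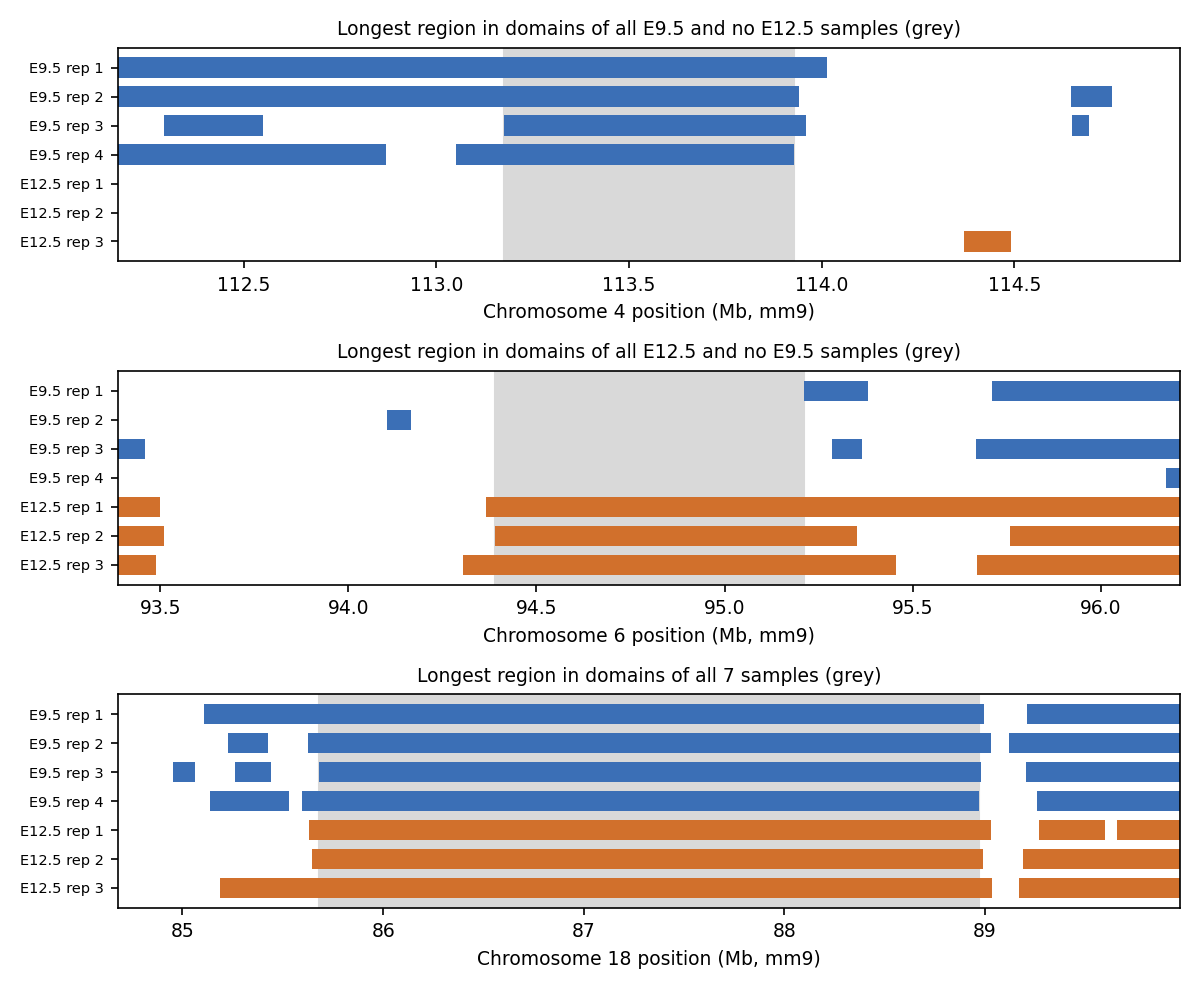
Called domains of each sample (blue, E9.5; orange, E12.5) along mm9 positions in Mb, with 1.0 Mb shown on each side. Grey marks the longest region in the domains of all E9.5 and no E12.5 samples (754 kb, chromosome 4), of all E12.5 and no E9.5 samples (821 kb, chromosome 6) and of all 7 samples (3289 kb, chromosome 18).

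Age-specific regions were spread unevenly over the chromosomes. Chromosome 4 had 3.40 Mb held at E9.5 and absent at E12.5, against 1.30 Mb in the other direction. Chromosome 13 had 2.74 against 0.651 Mb, and chromosome 1 had 2.55 against 1.61 Mb. The reverse held on chromosome 15, with 0.121 Mb specific to E9.5 and 1.40 Mb specific to E12.5. Chromosome 18 had 0.080 against 0.896 Mb, and chromosome 19 had 0.040 against 1.20 Mb. On the X, 2.04 Mb in 9 regions were specific to E12.5 and 0 Mb to E9.5. Chromosome 6 had similar lengths, 2.69 Mb specific to E9.5 and 2.27 Mb specific to E12.5. The 2 directions set unlike conditions, since 1 needs all 4 E9.5 samples and the other all 3 E12.5 samples. Over the whole genome the median of the other splits was 2.72 Mb for the 4-sample part and 3.40 Mb for the 3-sample part. These lengths were not tested chromosome by chromosome.

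The whole covered length was also compared by chromosome, and no chromosome passed adjustment over the 21. With a smallest possible p of 0.0286, none could pass unless most of the 21 reached it. The X had 7.70 Mb ± 4.92 (SD, n = 4) in domains at E9.5 and 21.2 Mb ± 1.55 (SD, n = 3) at E12.5, a ratio of 2.75. That is 4.62% and 12.7% of its length up to the furthest domain end. The E9.5 samples had 3.93 to 14.7 Mb, with E9.5 replicate 4 the highest, and the E12.5 samples had 19.7 to 22.8 Mb, so the ages did not overlap (exact permutation test, two-sided, p = 0.0571, adjusted 0.133). The E9.5 samples were pools of 3 litters and the E12.5 samples pools of 6 embryos. The list of E9.5 replicate 4 carries 0.12, the lowest number, as do those of E12.5 replicates 1 and 2. Chromosome 15 had 42.7 Mb ± 2.75 at E9.5 and 52.8 Mb ± 4.59 at E12.5 (exact permutation p = 0.0286, adjusted 0.12). Chromosome 18 had 23.4 Mb ± 3.16 and 31.3 Mb ± 2.69, and chromosome 19 had 14.8 Mb ± 1.64 and 18.9 Mb ± 0.564 (for each, exact permutation p = 0.0571, adjusted 0.133). Lower means at E12.5 were seen on chromosome 4, with 49.8 Mb ± 1.89 at E9.5 and 43.1 Mb ± 2.42 at E12.5, and on chromosome 10, with 48.8 Mb ± 1.23 and 44.0 Mb ± 2.33 (for each, exact permutation p = 0.0286, adjusted 0.12).

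In all, 5 of the 21 chromosomes had an unadjusted exact p of 0.0286 (chromosomes 4, 9, 10, 14 and 15), where 0.6 would be expected by chance, and 0 passed after Benjamini-Hochberg adjustment. That p is the smallest possible, and 5 chromosomes at it are too few for any to pass. The samples of the 2 ages did not overlap on 9 chromosomes, higher at E12.5 on 5 and lower on 4, where chance gives 5.71% or 1.2 chromosomes. The chromosomes are not independent, since they come from the same samples and share a nearly equal summed length. Whether these counts exceed chance was not tested. The Y had 2.00 Mb ± 0.345 at E9.5 and 1.93 Mb ± 0.288 at E12.5 (exact permutation p = 0.743).

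**Figure D4:**
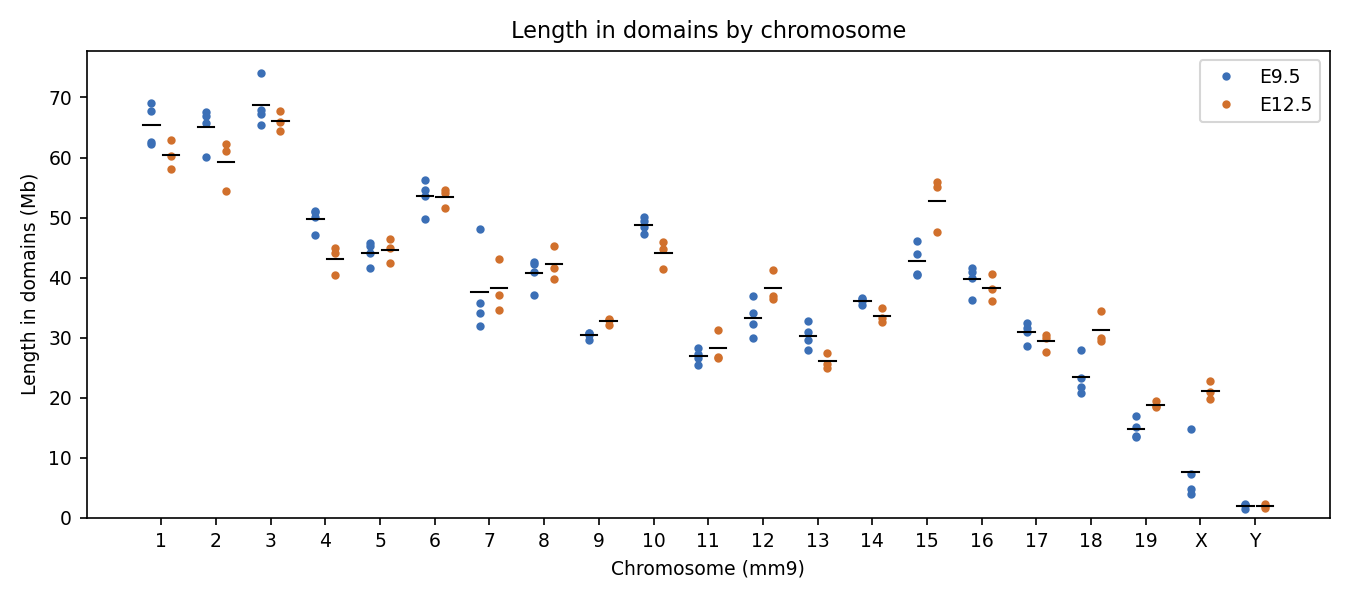
Length in domains (Mb) on each mm9 chromosome, with 1 point per sample (blue, E9.5, n = 4; orange, E12.5, n = 3) and a black bar at each mean. The X had 3.93 to 14.7 Mb at E9.5 and 19.7 to 22.8 Mb at E12.5; on chromosome 6 the means were 53.5 and 53.4 Mb.

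The spread of domain lengths differed between ages. Median domain length was 238.6 kb ± 7.89 (SD, n = 4) at E9.5 and 307.3 kb ± 2.08 (SD, n = 3) at E12.5, a difference of 68.7 kb (exact permutation test, two-sided, p = 0.0286, adjusted 0.0343). With only domains of at least 100 kb it was 32.5 kb, and the test was not passed (exact permutation p = 0.0571). Between group medians it was 66.5 kb (exact permutation p = 0.0571). With 4 and 3 samples that is the smallest p that group medians can give, so their test could not pass. E9.5 samples held more domains at both extremes. Domains under 150 kb numbered 510.5 ± 41.4 at E9.5 and 337.7 ± 12.5 at E12.5. Domains of at least 1 Mb numbered 226.8 ± 5.85 at E9.5 and 204.0 ± 9.85 at E12.5, and held 56.2% ± 1.70 and 46.8% ± 1.02 of the covered length. Domains between these lengths numbered 762.8 ± 42.2 at E9.5 and 958.3 ± 4.16 at E12.5. Each of these 4 measures had an exact permutation p of 0.0286, also after adjustment. The class counts sum to 1500 in every sample, and the share of length is tied to the longest class. The 4 measures thus describe the same shift in lengths and are not separate results. Domains under 150 kb, a limit chosen after seeing the data, were matched in other samples of the same age in 32.7% ± 3.05 of cases at E9.5 (SD, n = 4) and 34.8% ± 3.17 at E12.5 (SD, n = 3), where rotated domains gave 31.1% and 30.5%.

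**Figure D5:**
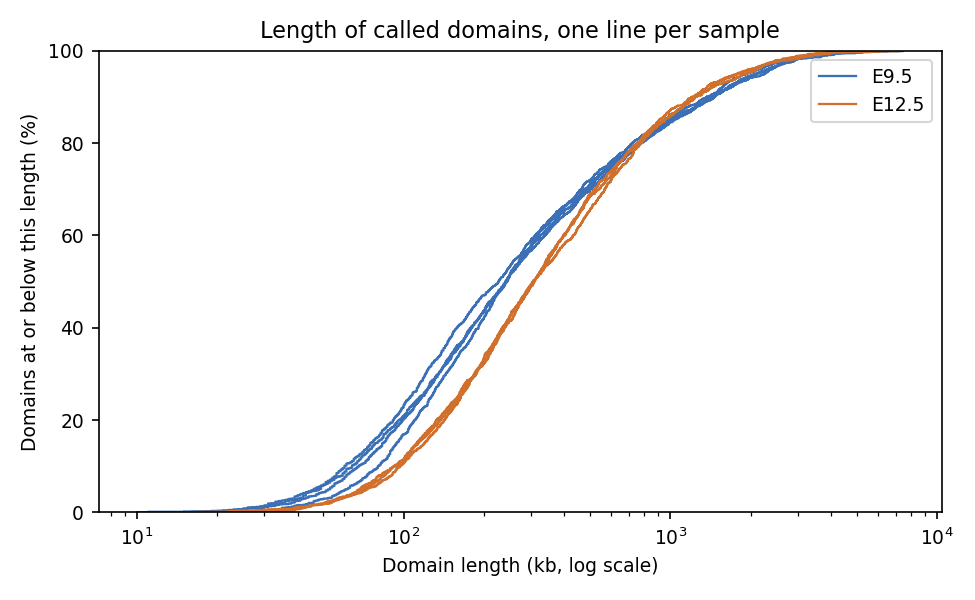
Share of the 1500 domains of each sample (y axis, %) at or below a given length (x axis, kb, log scale), with 1 line per sample. The E9.5 lines (blue) lie above the E12.5 lines (orange) at short lengths and below them at long lengths, with medians of 238.6 and 307.3 kb.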

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

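The tests of explanations for the X, for short calls and for the calling settings were chosen after the result was seen. The count of splits was planned, but its use as a test of chance was written after the result was seen. The tests on shifted edges and on split domains were set before their own values were seen, the latter after other tests of splitting had been tried. A single value stood apart within its group: E9.5 replicate 4 had 1.487 Mb of the Y in domains, where the other E9.5 samples had 2.10 to 2.23 Mb. Of 31 values checked this way in the E9.5 group, chance would place about 1.55 apart (1 in 20), so a single one is no more than chance gives.

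The X chromosome had 2.75 times as much length in domains at E12.5 as at E9.5. With 1 sample left out the ratio was at least 2.36. On the other chromosomes the ratios of E12.5 to E9.5 lay between 0.859 and 1.34. The X made up 0.977% ± 0.632 (SD) of the covered length at E9.5 and 2.63% ± 0.206 at E12.5. That is a ratio of 2.70 (exact permutation p = 0.0571). The X thus rose by a larger factor than any other chromosome. A general rise in called length may be hidden by the nearly equal summed length of the lists, so these values cannot decide on it. A calling setting that differs between samples remains open. The lists carry a number of unstated meaning, and among the samples with the lowest (0.12), 1 of E9.5 and 2 of E12.5, the X differed by 7.14 Mb, where all samples gave 13.5 Mb. The E9.5 lists with 0.17, 0.15, 0.14 and 0.12 had 4.74, 3.93, 7.38 and 14.7 Mb of the X. At E12.5 the list with 0.13 had 19.7 Mb, and those with 0.12 had 20.9 and 22.8 Mb. A different balance of male and female embryos in pools of 3 litters and of 6 embryos may change the dose of the X and remains open. The Y, which would move the other way, differed by -0.0657 Mb (exact permutation p = 0.743), but its domains are confined to less than 3 Mb. Within E9.5, replicate 4 had both the most X (14.7 Mb) and the least Y (1.487 Mb) in domains, the direction that a larger share of female embryos would give. This link was not tested, and E9.5 replicate 4 is also the sample of E9.5 whose list carries 0.12. E12.5 replicate 3 went the other way, with 2.22 Mb of the Y but 19.7 Mb of the X, more than any E9.5 sample. E12.5 replicates 1 and 2 had 1.65 and 1.93 Mb of the Y. A change of the X in development, which the design varies together with the kind of pool, was not tested separately.

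The 68.7 kb longer median domain at E12.5 was weighed against explanations that lie in the calling. Finer splitting of the same domains at E9.5 remains open. Of the E9.5 domains shorter than the E12.5 median of 307.3 kb, which exceeded 50% of the domains by 129 ± 14.1, on average 112.6 ± 18.2 (SD, n = 4) shared 1 E12.5 domain with another domain of their own sample. That is below the excess on average. At E12.5 the limit leaves no excess by construction, yet 99.7 ± 5.74 (SD, n = 3) likewise shared 1 E9.5 domain. Most of the E9.5 count may thus arise without finer splitting, and the count cannot decide. A larger number of short calls that do not recur may also account for the longer median. E9.5 domains under 150 kb were matched in other E9.5 samples only 1.60 ± 3.29 percentage points (SD, n = 4) above rotated domains. One sample reached 5.75 points, above the 5 points set as the limit, so this stays open. A calling setting that differs between samples stays open too. The E9.5 sample and the 2 E12.5 samples whose lists carry 0.12 differed by 80 kb, no less than all samples, but a single E9.5 sample and a number of unstated meaning exclude nothing. For a difference in read depth the lists hold no value.

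The age-specific regions were the third pattern. For both directions 1 of the 35 splits, the real one, gave as much length (26.8 Mb against at most 12.2 Mb, and 24.6 Mb against at most 13.2 Mb), so the split by age stood out at the 5% level. This is the count already given above and not a further test, and it is at the smallest share that 35 splits allow. The highest other splits were still close to the ages, with E9.5 replicate 1 or E9.5 replicate 3 moved to the E12.5 samples. Shifted edges of domains held at both ages do not account for all of it. Of the age-specific length, 33.3% lay in regions with bases in domains of at least 2 samples of the other age within 50 kb, and a wide uncertain edge may still add to this. Regions with no domain of any sample of the other age within 50 kb made up 22.5% of the E9.5-specific and 26.9% of the E12.5-specific length. A difference between the kinds of pool or in the calling settings remains open beside a difference between ages.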

How the results depend on the processing

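The direction of each main difference held under every alternative run, except for the covered length, which had not passed its test and turned to -1.54 Mb on chromosomes 1 to 19 alone because the X was left out. The overlap, matched-domain and age-specific results passed their test under each alternative that kept all 7 samples. The median domain length did not. Its difference was 32.5 kb among domains of at least 100 kb (exact permutation p = 0.0571), 0.333 kb among those of at least 150 kb (p = 1; this limit, chosen after seeing the data, removes the class in which E9.5 has more domains, so it does not show where the difference lies) and 66.5 kb between group medians (p = 0.0571). Group medians of 4 and 3 samples can give no p under 0.0571, so their test could not pass. With the replicate number as a block the difference in median length was 64.8 kb over 3 pairs, where the smallest p is 0.25 and no test can pass. The replicate numbers did not pair the samples: deviations from the age means correlated by -0.0176 to 0.003 between same-numbered samples (100-kb bins), and 1 of 3 E12.5 samples correlated best with its own number. Leaving out a sample takes every test to 0.05 or above by construction (smallest p 0.0667 without an E12.5 sample, and without an E9.5 sample 0.1, or 0.05 for an age-specific length). The differences then ranged from 6.31 to 18.03 Mb for the covered length, 64.8 to 70.7 kb for the median, 0.0718 to 0.105 for the overlap and 4.57 to 5.79 points for matched domains. E9.5-specific length ranged from 30.9 to 44.6 Mb and E12.5-specific length from 31.7 to 48.1 Mb, since each sample left out removes a condition. Without E12.5 replicate 1, 2 or 3 they were 41.8, 44.6 and 40.6 Mb, and 47.6, 47.9 and 48.1 Mb. Allowing 1 exception per age gave 149.5 and 180.1 Mb, where the highest other splits gave 127.0 and 130.3 Mb. Joining domains less than 50 kb apart removed 0.333% to 2.07% of the domains and so tests little. The number of chromosomes with an unadjusted p under 0.05 was 5, and 4 among domains of at least 100 kb. The covered length on the X differed by 12.2 to 15.8 Mb over its alternatives, none of which passed. The planned gene-level alternatives were not run, since genes were not placed on mm9.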

Other observations

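The test of a hypothesis in this part was planned before its values were seen, although not before the data were examined.

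Matching of domains rose with their length, within and between ages alike. Of E9.5 domains of at least 1 Mb, 85.6% ± 0.989 (SD, n = 4) were matched in an E12.5 sample and 95.4% ± 0.399 in other E9.5 samples, against 27.7% and 29.9% after rotation. For domains of 150 kb to 1 Mb the shares were 53.2% ± 4.08 and 59.8% ± 2.81, against 30.9% and 31.7% after rotation. For domains under 150 kb they were 32.6% ± 3.42 and 32.7% ± 3.05, against 31.0% and 31.1% after rotation. Short E9.5 domains thus recurred little above rotation even within their age, so their matching between ages does not show whether they were kept. E12.5 domains under 150 kb were matched in other E12.5 samples 4.28 ± 4.08 percentage points (SD, n = 3) above rotation, from 1.76 to 8.98 points.

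The distal ends of the chromosomes were compared between ages. Of the last 10 Mb before the furthest domain end of chromosomes 1 to 19 and the X, 25.5% ± 0.651 (SD, n = 4) was in domains at E9.5 and 22.4% ± 0.269 (SD, n = 3) at E12.5. The samples of the ages did not overlap (24.6% to 26.1% at E9.5, 22.1% to 22.6% at E12.5). The difference was -3.09 percentage points (exact permutation p = 0.0286, adjusted over both ends 0.0571). The unadjusted p is the smallest possible, so the distal end could not pass the adjustment unless the first 10 Mb reached it too. The chromosomes did not move together. The mean was lower at E12.5 on 11 of 20, most on chromosome 4 (29.6% at E9.5, 8.59% at E12.5) and chromosome 3 (66.3% and 48.9%). It was higher on the others, most on chromosome 1 (10.3% and 19.7%), chromosome 7 (8.31% and 17.5%) and chromosome 15 (10.8% and 16.5%). Without chromosome 4 the difference was -2.15 points. The first 10 Mb had 29.9% ± 2.07 and 31.3% ± 2.35 in domains (exact permutation p = 0.457). Unadjusted, the distal difference met the limit of 0.05 set beforehand. The adjustment could not decide and the chromosomes did not move together, so whether the distal ends differ between ages is left open.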
